A study of Mus musculus with 12 samples.

How the data were processed

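Bulk RNA sequencing was used to profile macrophages sorted by flow cytometry from the aorta and from adipose tissue of adult C57/BL6 mice. Per the labels, viable cells positive for CD45, CD64, MerTK, CD11b and F4/80 were sorted and divided by surface LYVE-1, a hyaluronan receptor of lymphatic endothelium that is also found on a subset of tissue macrophages. The aortic cells came from 30 mice and the adipose cells from the epididymal and subcutaneous fat of 20 mice, with n = 3 per group. Libraries were made by Smart-seq2, a full-length and unstranded protocol, from 2 ng of RNA and sequenced with paired reads of 51 cycles. The labels do not say whether the 3 libraries of a group came from separate pools of animals, so every p-value here measures the spread between these libraries only.

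The deposited count table holds raw counts, whole numbers for 46517 genes in 12 libraries, of which 25331 genes had a count in at least 1 library. The deposited expression table holds log2 CPM (counts scaled to the library size) for the same 25331 genes. It was checked against the counts and equalled the log2 CPM that edgeR gives with TMM factors and a prior count of 0.25, with a largest difference of 4.97e-14. STAR 2.5.2b, featureCounts 1.5.0, edgeR 3.14.0 and the genome build GRCm38 were named per the submitters' processing notes. The annotation release, the filters and the strand setting were not given in the sources used here. Genes that overlap another gene on the opposite strand, such as Npr1, Fcna, Vcam1, Cx3cr1, Cxcl16, Cdc20, Tk1, Mfap4 and Eln, were therefore not separated from their neighbour with certainty, and counts of close paralogs such as Hspa1a and Hspa1b or the Cd209 family depend on how multiply mapped reads were treated. Symbols and coordinates were taken from GENCODE M21 by Ensembl identifier, which gave a symbol to 46005 genes.

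The counts were tested with edgeR 4.0.16 in R 4.3.3. All 12 libraries entered a single quasi-likelihood fit with 1 mean per group, TMM factors and edgeR's filter on low counts, which kept 14216 genes and left 8 residual degrees of freedom. The comparisons were LYVE1+ against LYVE1- in each tissue, their average over tissues, their difference between tissues (the interaction), and aorta against fat within each sort. Tests were two-sided, with Benjamini-Hochberg adjusted p below 0.05 taken as a call. The standard error (SE) of a log2 fold change is its size divided by the square root of its F statistic. Levels per library are TMM-scaled CPM with the SD over 3 libraries, and sums over marker lists are CPM on the plain library size. Counting intervals and floors cover counting error only, since the reads carry no molecular identifiers. A fold against a group with no counts is given as a lower bound, from 3 counts over the whole group.

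Gene lists were fixed before the data were examined. They cover the gate, resident LYVE1+ macrophage genes, MHC class II presentation, monocyte and CCR2+ macrophage genes, hyaluronan, matrix proteases, scavenger receptors, complement, chemokines, inflammatory mediators, growth factors, immediate early and dissociation stress genes (immediate early genes below), type I interferon, cell cycle, lipid handling, iron and heme, glycolysis, oxidative phosphorylation and ribosomal proteins. The immediate early and dissociation stress list holds Hspa1a, Hspa1b, Egr1 and Egr2 among others. Whether differences in these genes reflect the dissociation of the tissue was not tested. Markers of dendritic, smooth muscle, fibroblast, endothelial, lymphatic endothelial, adipocyte, T and NK, B, neutrophil, mast, eosinophil, large peritoneal macrophage and erythroid cells were added to trace other cell types. A total of 31 lists with at least 4 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes. With this preset, splits of the same libraries into other groups called a median of 6 to 11 lists, depending on the comparison. The neutrophil list had 3 measured members and was not tested. Camera was run again with the correlation estimated from the data. This kept the cell cycle call in fat and in the interaction and ended every other list call, which can be read beside the unadjusted count: p was under 0.05 with the estimated correlation for 6 lists in the aorta, 1 in fat, 3 in the average, 4 in the interaction, 5 in LYVE1+ cells and 5 in LYVE1- cells.

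The genes named in the text were chosen by a rule written before the data were examined. For each LYVE1 comparison it took the 10 called genes with the largest fold change in each direction, with an average log2 CPM of at least 4 and no overlap between the 3 libraries of each group. For the interaction and the tissue comparisons it took 6 in each direction, the interaction without the overlap condition. From each list it added the up to 4 called members with the smallest adjusted p, or the 2 most abundant members where none was called, and the gate genes. Gene models without a name were skipped. Genes outside this rule are marked as chosen after their values were seen.

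Total counts per library ranged from 5.05 to 29.8 M. On simulated counts with the depths and spread of these libraries, the fit recovered 84 of 100 genes changed 4-fold and 33 of 100 changed 2-fold in the aorta, and 80 and 42 in fat. For the interaction it recovered 70 and 8. False calls made up 2.5% to 6.99% of the calls over the 6 comparisons. The changed genes all had an average of at least 4 CPM, and counts were drawn independently for each gene. These values therefore do not cover changes in genes of lower counts, or shifts of many genes together in a library.

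Pairs of libraries within a group had Pearson correlations from 0.907 to 0.965 across genes and none was a duplicate of another (lowest chi-square per degree of freedom 7.64). Whether equal replicate numbers mark a shared preparation was checked by correlating each library's deviations from its group mean. In fat, libraries of equal number correlated at 0.49, 0.28 and 0.18, although libraries 2 and 3 of different number did so too, at 0.19 and 0.22. In the aorta the equal-number values were -0.044, -0.077 and -0.17. A fit with the replicate number as a block is therefore printed beside the fat comparison and the interaction. Library identifiers carried 1 of 2 prefixes: all fat libraries and aorta LYVE1+ libraries 1 and 2 had RMM, and aorta LYVE1+ library 3 and all aorta LYVE1- libraries had RHH. What the prefix stands for was not given in the sources used here. It is partly confounded with the groups, so it was fitted as a covariate and, where possible, within a prefix. With this covariate the LYVE1 effect of the aorta, also within the average and the interaction, rests on a single LYVE1+ library, number 3. The prefix term itself is estimated only from aorta LYVE1+ cells, library 3 against libraries 1 and 2, also where LYVE1- cells of the tissues are compared.

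Alternatives covered DESeq2 size factors, plain library size, no low-count filter, a minimum of 5 CPM in at least 3 libraries, DESeq2 1.42.0, limma voom with quality weights, fits on the groups of a comparison alone, the replicate block, the prefix covariate, single-prefix subsets, a test against a 2-fold change (glmTreat) and leaving out each library. A fit without both fat libraries numbered 1 was added after seeing the data, because both stood apart in mitochondrial, erythroid and lymphocyte transcripts. Lists were not fitted with the prefix covariate, except the cell cycle list. All sample columns of the files were used. The labels state that 13 samples were sequenced, 12 on 1 Illumina instrument model and 1 on another, without saying which, and 12 libraries are in the files.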

Results

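Macrophages sorted from the mouse aorta and from adipose tissue were compared by their surface LYVE-1, with 3 libraries in each of the 4 groups. The gate asked for CD45, CD64, MerTK, CD11b and F4/80, so the 4 groups share a macrophage identity by sort. Transcripts of the gate genes Ptprc (the CD45 phosphatase of leukocytes), Fcgr1 (the CD64 Fc receptor), Mertk (a receptor for dying cells), Itgam (the CD11b integrin) and Adgre1 (F4/80) were not called different in any comparison of 2 groups. Csf1r, the receptor for the macrophage growth factor CSF1, was not called either. In the average over tissues Ptprc was called lower in LYVE1+ cells (log2 fold change -0.488, SE 0.13, adjusted p = 0.045). With the library prefix in the model it was not (-0.459, SE 0.17, adjusted p = 0.23). That call also ended without aorta LYVE1+ library 1 (0.11), 2 (0.089) or 3 (0.081), or without aorta LYVE1- library 1 (0.098). In fat it ended without LYVE1+ library 2 (0.12) or 3 (0.11) or LYVE1- library 1 (0.081), 2 (0.063) or 3 (0.075). Lyve1 (ENSMUSG00000030787.3, chromosome 7, 110850607 to 110863239), which encodes the sorted hyaluronan receptor, had 1928 ± 377 CPM in fat LYVE1+ cells and 470.2 ± 209 CPM in fat LYVE1- cells (mean ± SD, n = 3). It was 4.1-fold higher in the LYVE1+ cells of fat (log2 fold change 2.04, SE 0.33, adjusted p = 0.00383, edgeR). In the aorta the means were 2532 ± 423 and 1023 ± 260 CPM, a log2 fold change of 1.31 (SE 0.32) with every LYVE1+ library above every LYVE1- library, and the gene was not called (adjusted p = 0.108). The difference between the 2 tissues in this log2 fold change was -0.73 (adjusted p = 0.913).

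Blood, lymphocyte and fat-cell transcripts set 2 fat libraries apart. Fat LYVE1+ library 1 held 25900 CPM of erythroid markers (hemoglobin chains and Alas2, the heme enzyme of red-cell precursors) and fat LYVE1- library 1 held 5270 CPM. Mitochondrial transcripts made up 8.85% and 12.1% of their counts, against 1.79% to 3.2% in the other 10 libraries. Markers of T and NK cells summed to 279 and 144 CPM and adipocyte markers to 378 and 374 CPM. MHC class II transcripts, which encode the proteins that present antigen to helper T cells, summed to 13200 CPM in fat LYVE1+ library 1 and to 3280 and 3430 CPM in the other fat LYVE1+ libraries. The fat LYVE1- libraries had 46600 to 51800 CPM of them. Mast cell markers (Cpa3, Kit and tryptases) were at 47.4 to 80.4 CPM in aorta LYVE1- libraries and 1.84 to 12.7 CPM in aorta LYVE1+ libraries, and eosinophil markers at 47.1 to 147 against 5.05 to 5.47 CPM. Fibroblast markers (Col1a1, Dcn and other collagen-matrix genes) were at 894 to 2660 CPM in the aorta and 441 to 1110 CPM in fat.

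**Figure D1:**
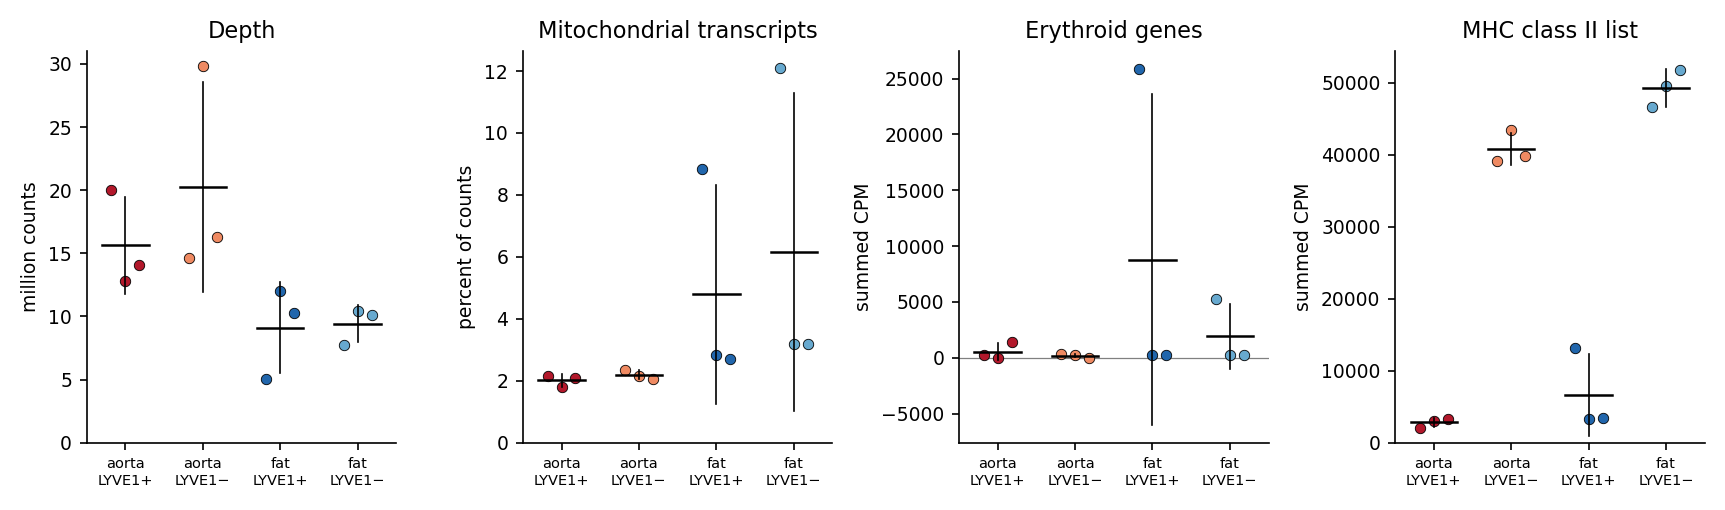
Depth in M counts, mitochondrial share of counts in percent, and the summed CPM of erythroid markers and of MHC class II genes in the 4 groups. Points are libraries, horizontal lines are group means and vertical lines are ± SD (n = 3).

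In the aorta, 7 of 10 class II genes were lower in LYVE1+ than in LYVE1- macrophages. Of 14 monocyte genes only Ccr2 was. Cd74, the invariant chain that guides class II molecules, and the class II chains H2-Aa, H2-Ab1 and H2-Eb1 were lower in LYVE1+ cells. Ccr2, the chemokine receptor that brings monocytes out of the marrow, Axl, a receptor for dying cells, and Egr2, a transcription factor of macrophage activation, were lower as well. Higher in LYVE1+ cells were Vsig4, a complement receptor of resident macrophages, and Aqp1, a water channel of endothelium and kidney. Of 14216 genes tested, 77 were called, 16 higher and 61 lower in LYVE1+ cells, and 69 of them differed by more than 2-fold. The balance was less one-sided with DESeq2 (122 higher and 238 lower) and without both fat libraries numbered 1 (236 and 330). The groups did not overlap for 22.4% of all genes, where chance gives 10%. The count was 27, 44 and 30 without aorta LYVE1+ libraries 1, 2 and 3, and 23 and 33 without aorta LYVE1- libraries 1 and 3. With only the aorta groups in the fit it was 294. Of the 33 calls among the genes named by rule, 10 held without each single library: Cd74, H2-Aa, H2-Ab1, H2-Eb1, H2-DMa, H2-DMb1, Ccr2, Axl, Grk3 and Egr2.

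Cd74 (ENSMUSG00000024610.13, chromosome 18, 60803848 to 60812652) had 1535 ± 315 CPM in aorta LYVE1+ cells and 18020 ± 2040 CPM in LYVE1- cells, 11.7-fold lower (log2 fold change -3.55, SE 0.37, adjusted p = 0.00141). H2-Eb1 (ENSMUSG00000060586.10, chromosome 17, 34305867 to 34316674) was 27.3-fold lower, with 199.9 ± 74 against 5458 ± 188 CPM (SE 0.62, adjusted p = 0.00478). Ccr2 (ENSMUSG00000049103.12, chromosome 9, 124101950 to 124113557) was 21.2-fold lower, with 10.6 ± 3.67 against 223.5 ± 79.4 CPM (SE 0.49, adjusted p = 0.00198). Axl was 4.84-fold lower (47.28 ± 27.3 against 228.4 ± 21.8 CPM, adjusted p = 0.00619). Vsig4 (ENSMUSG00000044206.3, chromosome X, 96247203 to 96293438) was 7.3-fold higher, with 60.99 ± 28.8 against 8.368 ± 2.76 CPM (SE 0.43, adjusted p = 0.0103). Aqp1 (ENSMUSG00000004655.5, chromosome 6, 55336432 to 55348555) was 7.59-fold higher, with 246.6 ± 33.5 against 32.47 ± 11.8 CPM (SE 0.46, adjusted p = 0.0136). The calls of Vsig4 and Aqp1 ended without aorta LYVE1- library 1 (adjusted p = 0.083 and 0.093).

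Adgrg1, an adhesion receptor of the G-protein-coupled class, was 4.81-fold higher in aorta LYVE1+ cells (log2 fold change 2.26, SE 0.38, adjusted p = 0.0178). Its call ended without LYVE1+ library 1 (adjusted p = 0.11) or 3 (0.065) and without LYVE1- library 1 (0.13) or 3 (0.1). Mmp12, the macrophage elastase, was 43.4-fold lower (log2 fold change -5.44, SE 0.88, adjusted p = 0.0137), and its call ended without LYVE1+ library 1 (0.12), 2 (0.066) or 3 (0.099) and without LYVE1- library 1 (0.055). Clec9a, a receptor of cross-presenting dendritic cells, had no counts in aorta LYVE1+ cells and was at least 67.4-fold lower, with 3 counts over the group as the floor (adjusted p = 0.032). It had 1.662 to 8.562 CPM in the aorta LYVE1- libraries, and its call ended in 5 of the fits that left out 1 aorta library. Mrc1, Cd163 and F13a1, markers used for resident perivascular macrophages, were not called in either tissue.

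The prefix of the library identifiers is nearly the same split as the sort in the aorta, since 2 LYVE1+ libraries carried RMM and the other 4 aortic libraries RHH. With the prefix in the model all 77 calls kept their sign, the median ratio of the log2 fold changes was 0.961, and the SE grew by a median ratio of 1.56. That effect rests on LYVE1+ library 3, the only RHH library of its sort, against the LYVE1- libraries. The groups did not overlap for any of the 77 genes, so the sign could not change and tells nothing of the prefix. Calls remained for 2 of the 77 genes, because the SE was larger and the fit had fewer libraries to tell sort from prefix. For Cd74 the log2 fold change moved from -3.55 (SE 0.37) to -3.37 (SE 0.61, adjusted p = 0.26), for Ccr2 from -4.4 (SE 0.49) to -4.64 (SE 0.85, adjusted p = 0.26), and for Vsig4 from 2.87 (SE 0.43) to 2.49 (SE 0.53, adjusted p = 0.31).

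Among the gene lists, MHC class II, oxidative phosphorylation and resident macrophage genes had the smallest adjusted p in the aorta. Of 10 class II genes, 7 were lower (8 adjusted over the list alone), such as Cd74 and H2-DMa, with a median log2 fold change of -3.1 (camera adjusted p = 8e-17, and adjusted p = 0.18 with an estimated correlation). All 22 resident LYVE1+ macrophage genes, such as Fcna, Vsig4 and Timd4, had positive values with a median of 0.57, 1 called higher and 9 over the list alone (adjusted p = 5.7e-09, and adjusted p = 0.35 with an estimated correlation). Of 83 oxidative phosphorylation genes, 79 had positive values and 1 (Ndufb9) was called, with a median of 0.28 (adjusted p = 1e-14, and adjusted p = 0.18 with an estimated correlation). Of 83 ribosomal protein genes 78 had negative values and none was called, with a median of -0.22 (adjusted p = 1.3e-05, and adjusted p = 0.61 with an estimated correlation).

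Inflammatory and monocyte lists were also called lower in aorta LYVE1+ cells, neither of them with an estimated correlation. Of 16 inflammatory genes 15 had negative values, 1 was called lower and 5 over the list alone, with a median of -0.58 (adjusted p = 2.3e-06, and adjusted p = 0.21 with an estimated correlation). Of 14 monocyte and CCR2+ macrophage genes 1 (Ccr2) was lower, 2 were higher and 7 lower over the list alone, with a median of -1.6 (adjusted p = 5.6e-05, and adjusted p = 0.35 with an estimated correlation). Of 23 matrix proteases 2 (Mmp12 and Mmp19) were lower, 4 over the list alone, with a median of -0.39 (adjusted p = 0.012, and adjusted p = 0.18 with an estimated correlation). Markers of other cell types moved with them: mast cell markers (6 measured, none called, 6 lower over the list alone, median -4, adjusted p = 5.2e-07), eosinophil markers (6 measured, 2 lower, 3 over the list alone, median -3.5, adjusted p = 5.9e-06) and dendritic cell markers (13 measured, 1 lower, 1 over the list alone, median -0.59, adjusted p = 0.00029). For each of these 3 lists it was adjusted p = 0.18 with an estimated correlation.

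Further lists were called in the aorta with all libraries and not without single ones. Of 21 chemokine genes 2 (Ccl22 and Cxcl16) were lower, 4 over the list alone (median -0.53, adjusted p = 0.0048; adjusted p = 0.35 with an estimated correlation), with 0.077 without LYVE1+ library 2. Of 5 lymphatic endothelial markers none was called, 3 higher over the list alone (median 3.2, adjusted p = 0.0078; adjusted p = 0.21 with an estimated correlation), with 0.058 without LYVE1+ library 2. Complement genes (14 measured, none called, median 0.4, adjusted p = 0.022; adjusted p = 0.58 with an estimated correlation) gave 0.065 without LYVE1+ library 2 and 0.093 without LYVE1- library 1. Of 19 lipid handling genes 2 (Pparg and Lpl) were lower, 1 higher and 4 lower over the list alone (median -0.51, adjusted p = 0.023; adjusted p = 0.21 with an estimated correlation), with 0.061 and 0.067 without LYVE1+ and LYVE1- library 3. Fibroblast markers (10 measured, none called, median -0.34, adjusted p = 0.023; adjusted p = 0.58 with an estimated correlation) gave 0.35, 0.19, 0.12 and 0.094 without LYVE1+ libraries 1 and 3 and LYVE1- libraries 2 and 3. B cell markers (8 measured, none called, median -1.3, adjusted p = 0.028; adjusted p = 0.56 with an estimated correlation) gave 0.16 and 0.13 without LYVE1+ and LYVE1- library 2.

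The remaining called lists of the aorta lay near the threshold. Of 24 immediate early genes 1 (Egr2) was lower, 1 over the list alone (median -0.16, adjusted p = 0.034; adjusted p = 0.58 with an estimated correlation), with 0.059, 0.075, 0.13 and 0.11 without LYVE1+ libraries 1 and 2 and LYVE1- libraries 2 and 3. T and NK cell markers (13 measured, none called, 3 lower over the list alone, median -0.68, adjusted p = 0.044; adjusted p = 0.65 with an estimated correlation) gave 0.21, 0.09 and 0.13 without LYVE1+ libraries 1 and 2 and LYVE1- library 3. Hyaluronan genes (13 measured, none called, 3 higher over the list alone, median 0.44, adjusted p = 0.049; adjusted p = 0.21 with an estimated correlation) gave 0.15, 0.078, 0.13 and 0.094 without LYVE1+ libraries 2 and 3 and LYVE1- libraries 2 and 3.

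In fat, 12 of 22 resident macrophage genes were higher in LYVE1+ than in LYVE1- macrophages. Lower were 16 of 22 cell cycle genes and 7 of 10 class II genes. Higher were Adgrg1, Vsig4, Npr1, a natriuretic peptide receptor, Fcna, a ficolin that starts the lectin pathway of complement, Timd4, a phosphatidylserine receptor of resident macrophages, Colec12, a scavenger collectin, and C2, a complement protease. Lower were Cd74, Ccr2, Cx3cr1, the fractalkine receptor of monocyte-derived cells, Vcam1, an adhesion molecule for leukocytes, Axl, and Fcgr4, an activating Fc receptor. Mki67, Tk1 and Rrm2, which mark dividing cells and DNA synthesis, were lower as well. Of 14216 genes 558 were called, 259 higher and 299 lower, 405 of them by more than 2-fold, and the groups did not overlap for 18.9% of genes where chance gives 10%. The count was 1025 without fat LYVE1+ library 1, 219 and 235 without fat LYVE1+ libraries 2 and 3, and 324 without fat LYVE1- library 3. Libraries of equal number deviated together in fat, and with the number as a block 915 genes were called. With only the fat groups in the fit 206 were called, and with only the aorta groups in theirs 294. Which tissue had more calls thus depended on the libraries fitted together. In the fit of the fat groups alone 28 of the 67 calls among the genes named by rule ended. Of the 67 calls among the genes named by rule 40 held without each single library, among them all of those listed above.

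Adgrg1 (ENSMUSG00000031785.14, chromosome 8, 94974751 to 95014217) had 122.5 ± 54.9 CPM in fat LYVE1+ cells and 4.101 ± 1.38 CPM in LYVE1- cells, 29.7-fold higher (log2 fold change 4.89, SE 0.44, adjusted p = 0.000243). Vsig4 was 22.5-fold higher (40.6 ± 20.7 against 1.805 ± 0.309 CPM, adjusted p = 0.00052) and Npr1 (ENSMUSG00000027931.11, chromosome 3, 90450591 to 90465866) 18-fold higher (57.59 ± 15.3 against 3.277 ± 1.93 CPM, SE 0.38, adjusted p = 0.000243). Fcna was 7.04-fold higher (2987 ± 1000 against 424.1 ± 223 CPM, adjusted p = 0.00271). Cd74 was 6.64-fold lower (3192 ± 2020 against 21180 ± 2400 CPM, SE 0.36, adjusted p = 0.00115). Cx3cr1 (ENSMUSG00000052336.6, chromosome 9, 119901616 to 120069879) was 16.4-fold lower (5.051 ± 3.52 against 76.84 ± 10.4 CPM, SE 0.56, adjusted p = 0.00158). Vcam1 was 8.68-fold lower (44.44 ± 16 against 383.1 ± 63.2 CPM, SE 0.24, adjusted p = 9.63e-05). Mki67 (ENSMUSG00000031004.7, chromosome 7, 135689784 to 135716361) was 3.73-fold lower (23.81 ± 6.05 against 88.2 ± 11.2 CPM, SE 0.21, adjusted p = 0.00047). Il12b, a subunit of the T cell cytokine IL-12, had no counts in fat LYVE1+ cells and was at least 18.8-fold lower, with 3 counts over the group as the floor.

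**Figure D2:**
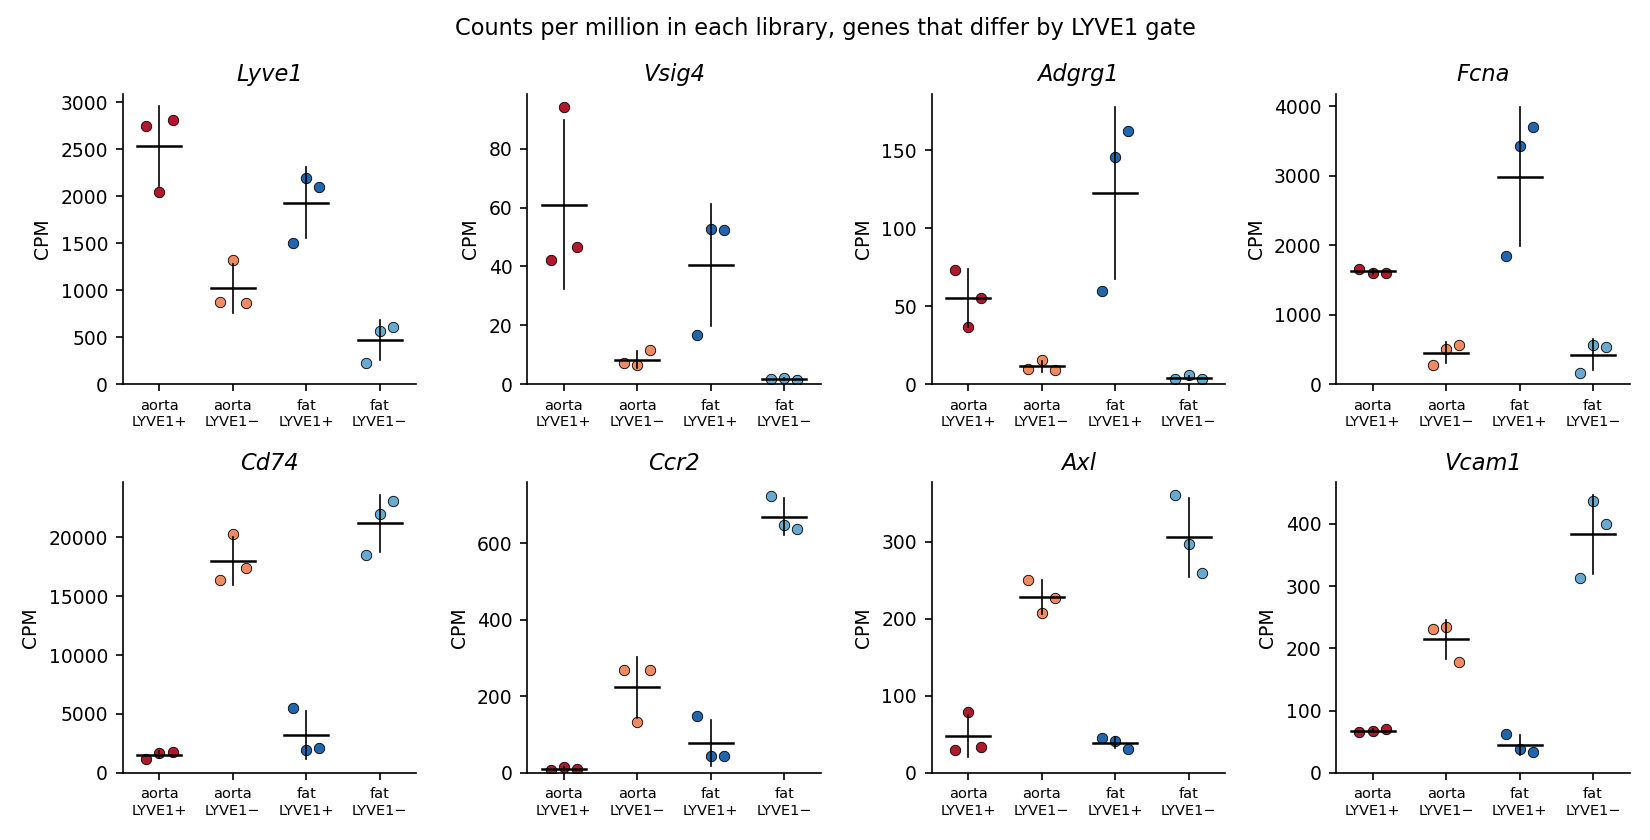
Expression in CPM of 4 genes higher (Lyve1, Vsig4, Adgrg1, Fcna) and 4 lower (Cd74, Ccr2, Axl, Vcam1) in LYVE1+ than LYVE1- macrophages of fat. Points are libraries of the 4 groups, horizontal lines are group means and vertical lines are ± SD (n = 3).

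Cell cycle genes gave the clearest list result in fat. Of 22 measured, 16 were lower in LYVE1+ cells (22 over the list alone), such as Mki67, Tk1, Rrm2 and Cdc20, with a median log2 fold change of -1.5 (camera adjusted p = 2.8e-25, and adjusted p = 0.041 with an estimated correlation). Of 22 resident macrophage genes 12 were higher (18 over the list alone), such as Fcna and Timd4, with a median of 1.3 (adjusted p = 5.8e-16, and adjusted p = 0.5 with an estimated correlation). Of 10 class II genes 7 were lower (7 over the list alone), with a median of -2.5 (adjusted p = 6.3e-10, and adjusted p = 0.5 with an estimated correlation). Ribosomal protein genes had 78 of 83 negative values, none called, and a median of -0.27 (adjusted p = 6.7e-08, and adjusted p = 0.77 with an estimated correlation). Of 16 inflammatory genes 4 were lower (7 over the list alone), such as Il1rn and Ptgs2, with a median of -1.1 (adjusted p = 2e-06, and adjusted p = 0.5 with an estimated correlation). Ptgs2 was not called without fat LYVE1+ library 2 (0.067) or 3 (0.069), and Il1rn without those (0.12 for each) or fat LYVE1- library 1 (0.088).

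Monocyte, complement and iron genes completed the called lists in fat. Of 14 monocyte and CCR2+ macrophage genes 3 were lower (6 over the list alone), such as Ccr2 and Cx3cr1, with a median of -1.3 (adjusted p = 0.00013, and adjusted p = 0.56 with an estimated correlation). Of 14 complement genes 3 (C2, C4b and C6) were higher (6 over the list alone), with a median of 0.53 (adjusted p = 0.00022, and adjusted p = 0.56 with an estimated correlation). C4b was not called without fat LYVE1+ library 2 (0.053), and C6 without fat LYVE1+ library 2 (0.079) or 3 (0.074) or fat LYVE1- library 3 (0.05). Of 12 iron and heme genes 1 was higher, Blvrb, which reduces biliverdin, with 3 higher and 1 lower over the list alone and a median of 0.34 (adjusted p = 0.046, and adjusted p = 0.61 with an estimated correlation). This list gave 0.085 and 0.1 without fat LYVE1+ libraries 2 and 3 and 0.18 without fat LYVE1- library 1.

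Averaged over the tissues, 16 of 22 resident macrophage genes were higher in LYVE1+ macrophages and 7 of 10 class II genes lower. The lower cell cycle genes of the average came from fat, with a median log2 fold change of -1.51 there and 0.133 in the aorta, where 14 of 22 members had positive values and the list was not called (adjusted p = 0.26). In all 901 genes were called, 413 higher and 488 lower, 429 of them by more than 2-fold. The count was 545 without aorta LYVE1+ library 1, 494 without aorta LYVE1- library 1, and 1635, 497 and 497 without fat LYVE1+ libraries 1, 2 and 3. With the prefix in the model it was 278, 272 of them among the 901, and the 901 log2 fold changes kept their sign with a median ratio of 0.992 while the SE grew by a median ratio of 1.25. Of 22 resident macrophage genes 16 were higher (18 over the list alone, median 0.91, adjusted p = 2.3e-15; adjusted p = 0.34 with an estimated correlation), of 10 class II genes 7 were lower (8, median -2.6, adjusted p = 1.6e-13; adjusted p = 0.34 with an estimated correlation), and of 22 cell cycle genes 12 were lower (19, median -0.64, adjusted p = 1.2e-13; adjusted p = 0.25 with an estimated correlation). Of 16 inflammatory genes 7 were lower, among them Il1b, an inflammasome-processed cytokine, and Nlrp3, its sensor (10 over the list alone, median -0.91, adjusted p = 1.1e-07; adjusted p = 0.34 with an estimated correlation). Of 14 monocyte genes 5 were lower, among them Ccr2, Cx3cr1 and Itgax (5, median -1.7, adjusted p = 9.3e-06; adjusted p = 0.34 with an estimated correlation).

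Other lists were called in the average with fewer called members. Ribosomal protein genes (83 measured, 2 lower, none over the list alone, median -0.26, adjusted p = 4.7e-09; adjusted p = 0.52 with an estimated correlation) and oxidative phosphorylation genes (83, 2 higher, 1 over the list alone, median 0.19, adjusted p = 2.2e-08; adjusted p = 0.34 with an estimated correlation) were called with the preset correlation alone, with small medians. Complement genes (14, 4 higher, 8 over the list alone, median 0.5, adjusted p = 0.00021), chemokines (21, 1 higher and 3 lower, 2 and 9 over the list alone, median -0.6, adjusted p = 0.008), iron and heme genes (12, 2 higher and 1 lower, 6 and 1 over the list alone, median 0.25, adjusted p = 0.02) and mast cell markers (6, 1 lower, 1 over the list alone, median -1.2, adjusted p = 0.011) each had adjusted p = 0.35 with an estimated correlation. Eosinophil markers (6, 1 lower, 1 over the list alone, median -2.4, adjusted p = 0.0034) and lymphatic endothelial markers (5, 3 higher, 4 over the list alone, median 3.4, adjusted p = 0.0059) had adjusted p = 0.34 with an estimated correlation. The lymphatic endothelial, eosinophil and mast cell lists each hold 2 members with no counts in a group, so these fitted medians are no bounds. Fibroblast markers (10, 1 lower, 1 over the list alone, median -0.35, adjusted p = 0.017; adjusted p = 0.54 with an estimated correlation) gave 0.078 and 0.062 without aorta LYVE1+ libraries 1 and 3 and 0.072 without fat LYVE1- library 1. Lipid handling genes (19, 1 higher and 7 lower, 2 and 9 over the list alone, median -0.49, adjusted p = 0.032; adjusted p = 0.34 with an estimated correlation) gave 0.05 without aorta LYVE1- library 3 and 0.19 without fat LYVE1+ library 1.

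Most genes called for LYVE1 in 1 tissue had the same sign in the other. Of 581 genes called in either tissue, 54 were called in both. Class II genes, Ccr2, Axl, Vcam1, Ccl22, a chemokine for regulatory T cells, and Pparg, a regulator of lipid uptake, were lower in LYVE1+ cells of both tissues, and Vsig4, Adgrg1, Npr1, Sema6a and Mctp2 were higher. In the aorta the calls of Cd74, H2-Aa, H2-Ab1, H2-Eb1, Ccr2 and Axl held without each single library. Leaving out 1 aorta library ended that of Mctp2 in 6 fits, Npr1 and Ccl22 in 5, Sema6a, Pparg and Adgrg1 in 4, and Vsig4 in 1. With the prefix in the model the calls of all these genes in the aorta ended. In all 54 genes were called in both, 12 higher (0.292 expected for independent lists) and 42 lower (1.28 expected), with 0 in opposite directions. Of the 77 calls of the aorta 75 had the same sign in fat, and of the 558 calls of fat 469 had the same sign in the aorta. Over all genes the log2 fold changes correlated with r = 0.31 (jackknife SE 0.23, Spearman 0.348), and the 2 comparisons share no library. With a minimum of 5 CPM in at least 3 libraries r was 0.525. The correlation was 0.102 without fat LYVE1- library 1, 0.187 and 0.184 without fat LYVE1+ libraries 2 and 3, and 0.231 to 0.406 without each of the others.

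**Figure D3:**
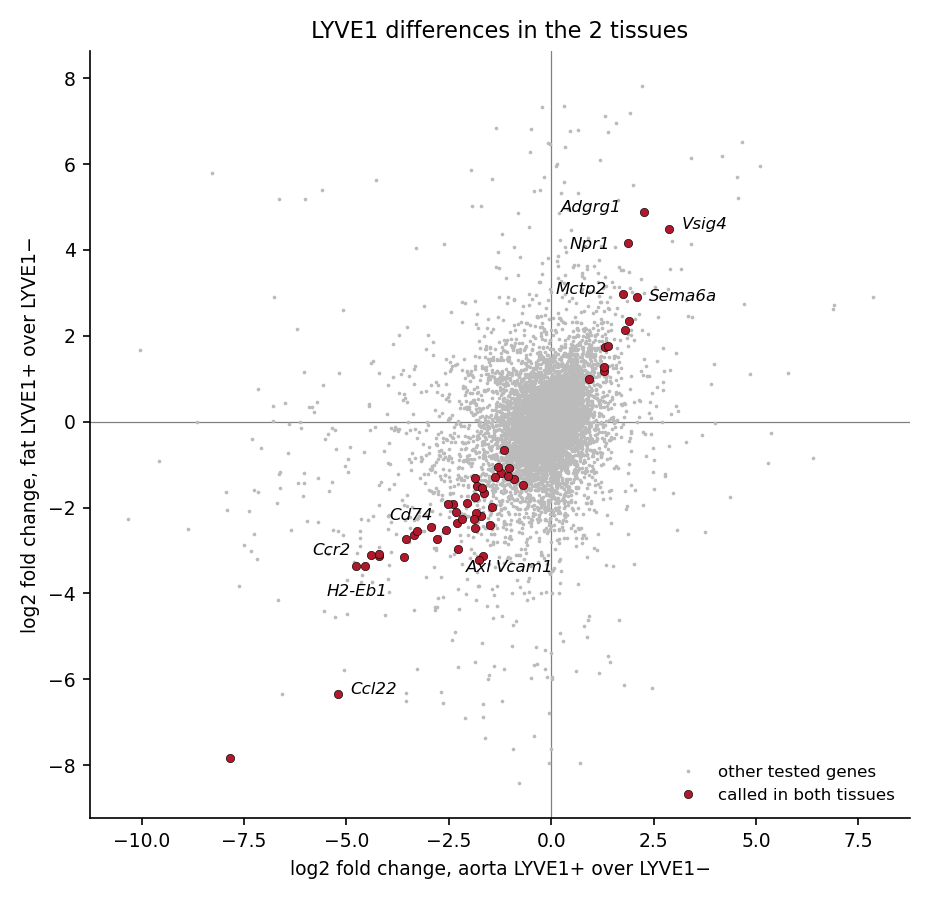
Log2 fold change of LYVE1+ over LYVE1- macrophages in the aorta against that in fat, 1 point per gene (14216 genes, r = 0.31). Red points are the 54 genes called in both tissues.

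The LYVE1 effect differed between tissues for genes of cell division. Hmmr, a hyaluronan receptor bound to the mitotic spindle, Cdc20, an activator of the anaphase complex, Tk1 and Stmn1 had higher values of the difference (aorta effect minus fat effect), and Siglech, a sialic acid receptor of plasmacytoid dendritic cells and microglia, a lower one. Mki67 had 71.83 ± 10.7 and 75.71 ± 13.7 CPM in aorta LYVE1+ and LYVE1- cells, and 23.81 ± 6.05 and 88.2 ± 11.2 CPM in fat, a difference in log2 fold change of 1.83 (SE 0.28, adjusted p = 0.0234). For Hmmr it was 3.2 (SE 0.47, adjusted p = 0.0206), and for Siglech, with 66 ± 3.69 against 20.31 ± 5.75 CPM in fat and 147.5 ± 3.33 against 143 ± 32.1 CPM in the aorta, it was -1.65 (SE 0.28, adjusted p = 0.0466). In all 22 genes were called, 21 higher and 1 lower. The balance was less one-sided with DESeq2 (78 higher and 30 lower) and without both fat libraries numbered 1 (61 and 23). Of the 22 cell cycle genes 10 were higher (18 over the list alone), all 22 had positive values and the median was 1.5 (camera adjusted p = 1.1e-33, and adjusted p = 0.016 with an estimated correlation).

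The count of 22 depended on which libraries were used. It was 0, 16 and 0 without aorta LYVE1+ libraries 1, 2 and 3, 0, 1 and 0 without aorta LYVE1- libraries 1, 2 and 3, 47, 0 and 5 without fat LYVE1+ libraries 1, 2 and 3, and 36, 0 and 0 without fat LYVE1- libraries 1, 2 and 3. For Hmmr the difference stayed from 2.9 to 3.43 in these fits. With the replicate number as a block 23 genes were called, 18 higher and 5 lower. Among them were 14 of the 22. Of the 10 called genes named by rule, Nusap1 (adjusted p = 0.091) and Siglech (0.052) were not called in that fit. With the prefix in the model edgeR called 0 genes, the 22 kept their sign with a median ratio of 0.991, and Hmmr moved from 3.2 (SE 0.47) to 3.02 (SE 0.55, adjusted p = 0.18). At an unadjusted p under 0.05 there were 862 genes with all libraries and 651 with the prefix. DESeq2 called 108.

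**Figure D4:**
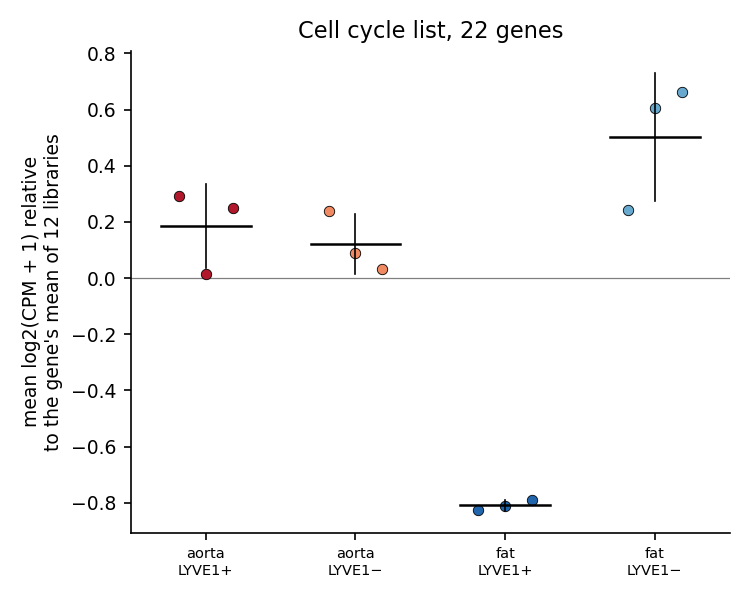
Mean over 22 cell cycle genes of log2(CPM + 1) relative to each gene's mean over libraries, in the 4 groups. Points are libraries, horizontal lines are group means and vertical lines are ± SD (n = 3).

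The other 7 lists called for this difference were not called with an estimated correlation. The mast, eosinophil and T and NK lists each hold 2 members with no counts in a group and the dendritic list 1, so these fitted medians are no bounds. Mast cell markers had a median of -5.8 (6 measured, none called, 6 lower over the list alone, adjusted p = 5.4e-07; adjusted p = 0.21 with an estimated correlation) and eosinophil markers one of -3.2 (6, none called, 1 over the list alone, adjusted p = 0.00013; adjusted p = 0.32 with an estimated correlation). Dendritic cell markers had a median of -0.83 (13, 1 lower, 3 over the list alone, adjusted p = 0.00051; adjusted p = 0.19 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.2 (83, none called, adjusted p = 5.5e-06; adjusted p = 0.78 with an estimated correlation). Resident macrophage genes such as Fcna had one of -0.47 (22, none called, 2 lower over the list alone, adjusted p = 3.1e-05; adjusted p = 0.99 with an estimated correlation) and gave 0.19 without fat LYVE1- library 1. B cell markers (8, none called, median -2.5, adjusted p = 0.014; adjusted p = 0.78 with an estimated correlation) gave 0.091 and 0.051 without aorta LYVE1+ and LYVE1- library 2, 0.3 without fat LYVE1+ library 1 and 0.053 without fat LYVE1- library 2. T and NK cell markers (13, none called, median -1, adjusted p = 0.017; adjusted p = 0.99 with an estimated correlation) gave 0.12, 0.05 and 0.063 without aorta LYVE1+ libraries 1 and 2 and aorta LYVE1- library 3, and 0.58, 0.21 and 0.097 without fat LYVE1+ library 1 and fat LYVE1- libraries 2 and 3.

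Between tissues, 12 of 22 cell cycle genes and 2 of 10 smooth muscle markers were higher in LYVE1+ macrophages of the aorta. In those of fat 4 of 10 adipocyte markers were higher. Higher in the aorta were Mfap4, a microfibril protein of elastic tissue, Aqp1, Cx3cr1, Ccl4, a chemokine that draws T cells and monocytes, Cxcl16, a scavenger chemokine, Osm, a cytokine of the IL-6 family, and Hspa1b, an inducible heat shock protein. Lower were Egr2, Pdk4, a kinase that spares glucose in favour of fat oxidation, Cfd, the adipsin of fat cells, Ccr2 and Cxcl12, a homing chemokine. In all 426 genes were called, 267 higher and 159 lower, 300 of them by more than 2-fold. The groups did not overlap for 20.6% of genes where chance gives 10%. The count was 193, 246 and 176 without aorta LYVE1+ libraries 1, 2 and 3, and 186 and 172 without fat LYVE1+ libraries 2 and 3. With the prefix in the model it was 181, 172 of them among the 426, and all 426 kept their sign with a median ratio of 0.989. That effect rests on the RMM libraries 1 and 2 of aorta LYVE1+ cells. The groups did not overlap for any of the 426 genes, so the sign could not change. Of the 56 calls among the genes named by rule 31 held without each single library, among them all of those listed above.

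Mfap4 (ENSMUSG00000042436.11, chromosome 11, 61485431 to 61488900) had 36.19 ± 21.1 CPM in aorta and 0.639 ± 0.656 CPM in fat LYVE1+ cells, 49.1-fold higher (log2 fold change 5.62, SE 0.56, adjusted p = 0.000347). Aqp1 was 26.6-fold higher (246.6 ± 33.5 against 9.941 ± 8.69 CPM, adjusted p = 0.000766) and Cx3cr1 15.5-fold higher (72.64 ± 51.4 against 5.051 ± 3.52 CPM, adjusted p = 0.00257). Cxcl16 (ENSMUSG00000018920.10, chromosome 11, 70453983 to 70459984) was 3.26-fold higher (270 ± 30.8 against 82.74 ± 3.38 CPM, SE 0.16, adjusted p = 0.000228). Ccl4 was 11.3-fold higher (1865 ± 1260 against 165.2 ± 9.17 CPM, adjusted p = 0.0022) and Hspa1b 19.9-fold higher (43.94 ± 4.59 against 2.201 ± 0.544 CPM, adjusted p = 3.81e-06). Egr2 (ENSMUSG00000037868.14, chromosome 10, 67535475 to 67542188) was 5.23-fold lower (40.77 ± 5.61 against 213.4 ± 6.33 CPM, SE 0.16, adjusted p = 1.21e-05). Cfd (ENSMUSG00000061780.5, chromosome 10, 79890853 to 79892655) was 19.6-fold lower (1.023 ± 0.191 against 20.24 ± 13 CPM, SE 0.58, adjusted p = 0.00229).

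Cell cycle genes had the smallest adjusted p of the lists in LYVE1+ cells of the 2 tissues. Of 22 measured 12 were higher (20 over the list alone), such as Mki67 and Stmn1, with a median of 1 (adjusted p = 4.6e-18; adjusted p = 0.11 with an estimated correlation). Adipocyte markers (10 measured, 4 lower, 7 over the list alone, median -3.1, adjusted p = 6.3e-07) had adjusted p = 0.28 with an estimated correlation, and smooth muscle markers (10, 2 higher, 5 over the list alone, median 1.5, adjusted p = 0.00028) had adjusted p = 0.35 with an estimated correlation. Growth factors (20, 2 higher, among them Pdgfa, a mitogen of smooth muscle, 5 over the list alone, median 0.4, adjusted p = 0.0032) had adjusted p = 0.19 with an estimated correlation. Hyaluronan genes (13, Hmmr higher, 6 over the list alone, median 0.53, adjusted p = 0.0036) had adjusted p = 0.11 with an estimated correlation. Lymphatic endothelial markers (5, none called, 2 over the list alone, median 2, adjusted p = 0.0038) had adjusted p = 0.28 with an estimated correlation. Fibroblast markers (10, 3 higher, among them Col1a1, 4 over the list alone, median 0.91, adjusted p = 0.0033; adjusted p = 0.56 with an estimated correlation) gave 0.074 without aorta LYVE1+ library 2.

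The other lists called in this comparison depended on fat LYVE1+ library 1, the library with more blood and lymphocyte transcripts. Without it class II genes (10 measured, none called, 4 lower over the list alone, median -1.5, adjusted p = 0.0036; adjusted p = 0.56 with an estimated correlation) gave 0.4, and eosinophil markers (6, none called, 2 over the list alone, median -2.9, -2.2 at bound, adjusted p = 0.019; adjusted p = 0.56 with an estimated correlation) gave 0.17. Monocyte genes (14, Cx3cr1 higher, Ccr2 and Plac8 lower, 2 and 8 over the list alone, median -2.4, adjusted p = 0.027; adjusted p = 0.57 with an estimated correlation) gave 0.45. B cell markers (8, 1 lower, 1 over the list alone, median -2.3, adjusted p = 0.027; adjusted p = 0.56 with an estimated correlation) gave 0.41, and 0.13 without aorta LYVE1+ library 2. Mast cell markers (6, none called, 1 over the list alone, median -2.2, adjusted p = 0.043; adjusted p = 0.56 with an estimated correlation) gave 0.41, and 0.091 and 0.14 without aorta LYVE1+ libraries 1 and 3. Inflammatory genes (16, 3 higher, among them Osm, 3 over the list alone, median 0.54, 0.36 at bound, adjusted p = 0.043; adjusted p = 0.57 with an estimated correlation) gave 0.083, and 0.56 and 0.086 without aorta LYVE1+ library 3 and fat LYVE1+ library 3.

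In LYVE1- macrophages 5 of 10 smooth muscle markers and 2 of 10 fibroblast markers were higher in the aorta. In fat 3 of 10 adipocyte markers were higher. Higher in the aorta were Mfap4, Eln, the elastin of the vessel wall, Mgp, an inhibitor of calcification, Osm, Ccl3 and Ccl4, Cxcl16, Hspa1b and Siglech. Lower were Egr2, Pdk4, Cfd and Bcam, a laminin receptor. In all 353 genes were called, 236 higher and 117 lower, 212 of them by more than 2-fold. The groups did not overlap for 21.1% of genes where chance gives 10%. The count was 154, 142 and 152 without aorta LYVE1- libraries 1, 2 and 3, and 153 and 98 without fat LYVE1- libraries 2 and 3. The prefix parts these 2 groups except for what aorta LYVE1+ cells tell of it, so with the prefix in the model 7 genes were called, all 7 among the 353. Of the 54 calls among the genes named by rule 21 held without each single library, among them Mfap4, Eln, Mgp, Osm, Ccl3, Cxcl16, Hspa1b, Siglech, Egr2, Pdk4, Cfd and Bcam. Ccl4 (adjusted p = 0.022) was not called without aorta LYVE1- libraries 1 and 2 (0.088 and 0.07) or fat LYVE1- libraries 2 and 3 (0.095 and 0.094).

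Eln (ENSMUSG00000029675.11, chromosome 5, 134702593 to 134747323) had 66.95 ± 19.2 CPM in aorta and 1.385 ± 0.659 CPM in fat LYVE1- cells, 47.9-fold higher (log2 fold change 5.58, SE 0.41, adjusted p = 3.55e-05). Mfap4 was 137-fold higher (44.99 ± 5.37 against 0.3162 ± 0.0736 CPM, SE 0.62, adjusted p = 6.48e-05), Hspa1b 10-fold higher (adjusted p = 3.27e-05) and Siglech 7.01-fold higher (adjusted p = 3.55e-05). Egr2 was 3.72-fold lower (90.53 ± 13 against 336.7 ± 43.8 CPM, adjusted p = 6e-05). These 5 genes stayed called with the prefix in the model, at adjusted p = 0.0092 for Eln, 0.024 for Mfap4, 0.0092 for Hspa1b, 0.03 for Siglech and 0.0092 for Egr2. Osm (ENSMUSG00000058755.3, chromosome 11, 4236420 to 4241026) was 3.25-fold higher (182.7 ± 13 against 56.18 ± 8.79 CPM, SE 0.17, adjusted p = 0.000248), and Cfd 14-fold lower (1.705 ± 1.08 against 24.82 ± 12.2 CPM, SE 0.55, adjusted p = 0.00354). With the prefix Osm moved from a log2 fold change of 1.7 (SE 0.17) to 1.26 (SE 0.27, adjusted p = 0.37), Ccl3 from 2.36 (SE 0.35) to 1.25 (SE 0.5, adjusted p = 0.75) and Ccl4 from 2.15 (SE 0.44) to 0.711 (SE 0.6, adjusted p = 0.92). Cxcl16 moved from 1.3 (SE 0.16) to 1.02 (SE 0.28), Cfd from -3.81 (SE 0.55) to -4.07 (SE 1.1), Mgp from 4.19 (SE 0.7) to 4.51 (SE 1.3) and Bcam from -1.97 (SE 0.29) to -1.99 (SE 0.54), each with adjusted p = 0.52. Pdk4 moved from -3.21 (SE 0.41) to -3.36 (SE 0.7, adjusted p = 0.31). Over the 353 genes the signs held, the log2 fold changes had a median ratio of 0.933 and the SE one of 1.83. The prefix term behind these shifts came only from aorta LYVE1+ library 3 against libraries 1 and 2. There Ccl4 had 3216 CPM in library 3 and 1664 and 713.3 CPM in libraries 1 and 2. The shifts are therefore no measure of the prefix within LYVE1- cells.

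**Figure D5:**
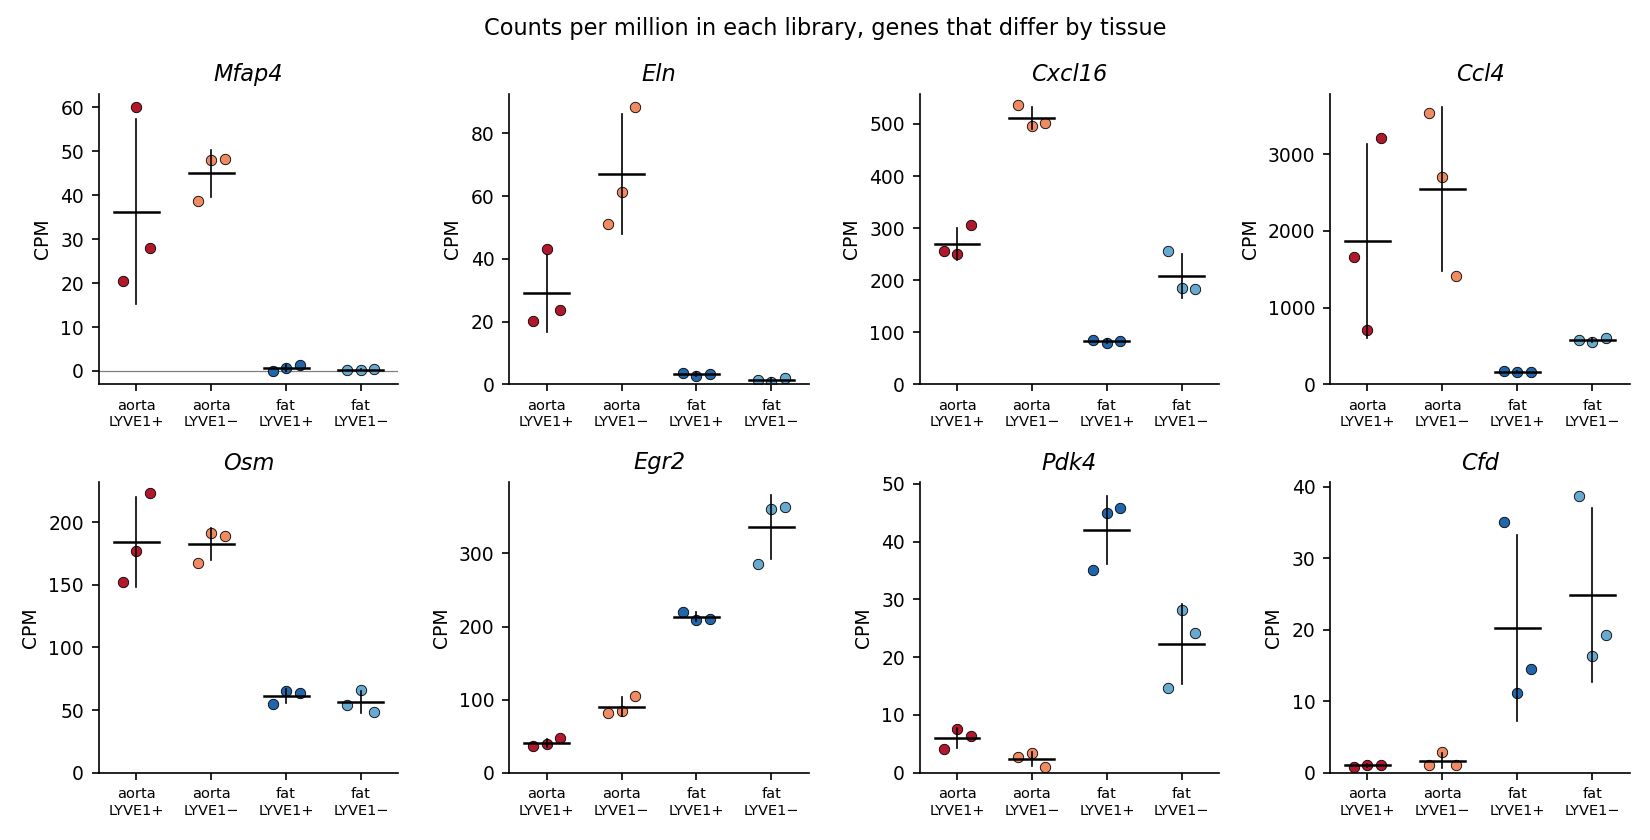
Expression in CPM of 5 genes higher (Mfap4, Eln, Cxcl16, Ccl4, Osm) and 3 lower (Egr2, Pdk4, Cfd) in libraries of sorted macrophages of the aorta than of fat. Points are libraries of the 4 groups, horizontal lines are group means and vertical lines are ± SD (n = 3).

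Several lists were called between the LYVE1- groups, none of them with an estimated correlation. Adipocyte markers (10 measured, 3 lower, 6 over the list alone, median -3, adjusted p = 2.9e-06), smooth muscle markers (10, 5 higher, among them Acta2 and Mylk, 7 over the list alone, median 1.9, adjusted p = 8.3e-06), cell cycle genes (22, Rrm2 lower, 7 over the list alone, median -0.41, adjusted p = 8.3e-06) and matrix proteases (23, Plau, the urokinase, higher, 2 over the list alone, median 0.47, adjusted p = 0.0038) each had adjusted p = 0.27 with an estimated correlation. Plau was not called without fat LYVE1- library 3 (0.051). Growth factors (20, 4 higher, among them Pdgfa and Bmp2, 7 over the list alone, median 0.48, adjusted p = 9.8e-05) had adjusted p = 0.21 with an estimated correlation. Pdgfa was not called without aorta LYVE1- library 3 (0.053) or fat LYVE1- libraries 2 and 3 (0.057 and 0.065). Oxidative phosphorylation genes (83, none called, median -0.17, adjusted p = 9e-05) and fibroblast markers (10, 2 higher, 4 over the list alone, median 0.97, adjusted p = 0.001) had adjusted p = 0.52 with an estimated correlation. Mast cell markers (6, none called, 5 higher over the list alone, median 3.3, adjusted p = 0.001) had adjusted p = 0.31 with an estimated correlation, and lymphatic endothelial markers (5, 1 higher, 1 over the list alone, median 2.9, 1.4 at bound, adjusted p = 0.015) had adjusted p = 0.3 with an estimated correlation.

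Resident, monocyte, hyaluronan, chemokine, lipid and scavenger lists were also called between the LYVE1- groups, and each of these calls ended without fat LYVE1- library 1. Without it resident genes (22, 3 higher, among them Vsig4, Timd4 and Stab1, 4 over the list alone, median 0.3, adjusted p = 0.002; adjusted p = 0.72 with an estimated correlation) gave 0.78, and monocyte genes (14, 1 lower, 1 higher and 4 lower over the list alone, median -0.98, adjusted p = 0.0047; adjusted p = 0.55 with an estimated correlation) gave 0.12. Hyaluronan genes (13, 3 higher, among them Hyal1 and Cemip2, 4 higher and 1 lower over the list alone, median 0.42, adjusted p = 0.026; adjusted p = 0.27 with an estimated correlation) gave 0.12, and 0.073 without aorta LYVE1- library 1. Chemokines (21, Ccl3, Ccl4 and Cxcl16 higher and Ccl6 lower, 6 and 1 over the list alone, median 0.54, adjusted p = 0.026; adjusted p = 0.52 with an estimated correlation) gave 0.12, and 0.082 without aorta LYVE1- library 1. Lipid handling genes (19, Fabp4 lower, 5 over the list alone, median -0.4, adjusted p = 0.026; adjusted p = 0.27 with an estimated correlation) gave 0.15, and 0.057 without aorta LYVE1- library 2. Scavenger receptors (17, 2 higher, 4 over the list alone, median 0.35, adjusted p = 0.037; adjusted p = 0.55 with an estimated correlation) gave 0.4, and 0.067 and 0.074 without aorta LYVE1- libraries 2 and 3.

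Most genes called between the tissues in 1 sort had the same sign in the other sort. Of 622 genes called in either sort, 157 were called in both. Mfap4, Hspa1b, Osm and Cxcl16 were higher in the aorta in both sorts, and Egr2, Pdk4, Cfd and Car3, a carbonic anhydrase of fat and muscle, were lower. Cfd and Car3 were highest in the fat libraries numbered 1, which held the most adipocyte markers (378 and 374 CPM). Mfap4 peaked in aorta LYVE1+ library 2 (60.13 CPM), as did fibroblast markers (2660 CPM). In aorta LYVE1- libraries 1, 2 and 3 Mfap4 had 38.79, 47.96 and 48.22 CPM, and fibroblast markers had 1410, 2370 and 1930 CPM. Library 1 was the lowest for both. Whether these transcripts came from macrophages or from other cells in the sort was not tested. In all 157 genes were called in both, 118 higher (4.43 expected for independent lists), 38 lower (1.31 expected) and 1 in opposite directions. Of the 426 calls in LYVE1+ cells 362 had the same sign in LYVE1- cells, and of the 353 calls in LYVE1- cells 336 had the same sign in LYVE1+ cells, with r = 0.475 over all genes (jackknife SE 0.14, 0.316 without fat LYVE1- library 1, and 0.43 to 0.497 without each of the others). The call of Car3 ended in LYVE1+ cells without aorta LYVE1+ libraries 1 and 3 (0.068 and 0.054) and in LYVE1- cells without aorta LYVE1- libraries 1 and 3 (0.064 for each). With the prefix the calls of Osm, Cxcl16, Pdk4, Cfd and Car3 in LYVE1- cells ended. Car3 moved from -3.24 (SE 0.58) to -3.78 (SE 1, adjusted p = 0.52) there, and from -3.02 (SE 0.58) to -3.23 (SE 0.71, adjusted p = 0.052) in LYVE1+ cells.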

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

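The tests of where the cell cycle difference comes from were chosen after the result was seen, and the other splits of the libraries were planned.

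Transcripts of cell cycle genes and of a sialic acid receptor differed between the tissues in their LYVE1 effect, by a test of the difference itself, with 22 genes and 8 lists called, of which only cell cycle stayed called with an estimated correlation. The difference in log2 fold change (aorta minus fat) was 3.2 for Hmmr, 2.38 for Nusap1, 2.3 for Cdc20, 2.17 for Tpx2, 2.16 for Tk1, 2.15 for Birc5, 2.02 for Prc1, 2 for Stmn1 and 1.7 for Mcm5, which serve the spindle, chromosome segregation or DNA replication. Siglech, the receptor of plasmacytoid dendritic cells and microglia, was at -1.65. The medians of the called lists were 1.5 for cell cycle, 0.2 for oxidative phosphorylation, -0.47 for resident macrophage genes, and for markers of other cells -0.83 (dendritic), -1 (T and NK), -2.5 (B), -5.8 (mast) and -3.2 (eosinophil). The mast, eosinophil and T and NK lists each hold 2 members with no counts in a group and the dendritic list 1, so these fitted medians are no bounds.

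Cell cycle genes were lower in LYVE1+ cells of fat (median log2 fold change -1.51) and near 0 in the aorta (0.133), a difference of 1.54 with all 22 genes above 0. The fat libraries numbered 1 as the cause are argued against, since without both the difference was 1.63 (adjusted p = 0.021 with an estimated correlation). A difference between the library prefixes is argued against for the fat part, since all fat libraries have 1 prefix and the lowest LYVE1- library lay 1.03 above the highest LYVE1+ library in mean log2 CPM. For the aorta part, where the prefix may hide a difference, it stays open: with matching prefixes the aorta median was 0.118 and the difference 1.62 (adjusted p = 0.09), and with the prefix in the model 1.62 (adjusted p = 0.049), but both rest on the single RHH library of aorta LYVE1+ cells. More division among LYVE1- macrophages of fat, or less among LYVE1+ ones, may be the biological source and was not tested.

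Other splits of the same libraries were counted for each comparison, the real split included. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. Real and highest other values were 77 and 1 genes in the aorta (1 split as large), 558 and 0 in fat (1), 426 and 0 in LYVE1+ cells (1) and 353 and 0 in LYVE1- cells (1). For lists they were 19 and 10 in the aorta (1), 8 and 18 in fat (4), 13 and 15 in LYVE1+ cells (4) and 15 and 14 in LYVE1- cells (1). The median of the other splits was 7, 6, 11 and 8 lists in that order. In fat the splits with 18, 15 and 9 lists put both libraries numbered 1 on the same side, which points to a structure of the samples. The other fat splits that parted every pair of equal number called 5, 4 and 5 lists.

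For the average over tissues 1 of 100 splits, the real one, was as large (901 genes, highest other 114), and 8 of 100 for lists (15, highest other 18, median of the others 8). A chance split of these libraries is thus argued against for the gene count, and not for the lists. The splits cannot tell the sort from the prefix, which nearly follows it in the aorta. Nor can they tell it from pools of animals, which the labels do not give. For the interaction 6 of 100 splits called as many genes (22, highest other 382) and 58 of 100 as many lists (8, highest other 19, median of the others 8), so chance is not excluded for these counts. Of the 5 other splits with as many genes, 4 exchanged most labels of 1 tissue, which turns the shared LYVE1 effect into a difference between tissues and points to a structure of the samples.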

How the results depend on the processing

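The fit without both fat libraries numbered 1 was chosen after the data were seen, and the others were planned.

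Counts of called genes are given in the order aorta, fat, average, interaction, LYVE1+ aorta against fat, LYVE1- aorta against fat, where they moved by more than 1.5 times from 77, 558, 901, 22, 426 and 353. DESeq2 gave 360, 1022, 1549, 108, 931 and 850, and voom with quality weights 267, 1364, 1794, 89, 947 and 965. Without both fat libraries numbered 1 they were 566, 887, 1571, 84, 890 and 1024, and 77, 488, 860, 22, 401 and 345 of the genes called with all libraries were among these. Against a 2-fold change they were 16, 55, 59, 0, 29 and 22. For the interaction, 0 genes were called there and 0 with the prefix, where 256 and 651 of 14216 genes had an unadjusted p under 0.05, against 862 in the fit with all libraries and no prefix, and 651 is less than that share of all genes.

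Without the low-count filter they were 336 (aorta), 72 (interaction), 820 (LYVE1+) and 647 (LYVE1-), and with only the groups of the comparison 294 (aorta), 206 (fat) and 243 (LYVE1+). The replicate block gave 243 (aorta), 915 (fat), 1470 (average), 199 (LYVE1+) and 160 (LYVE1-). The prefix as a covariate gave 2 (aorta), 278 (average), 0 (interaction), 181 (LYVE1+) and 7 (LYVE1-), RHH libraries alone 2 (aorta) and RMM libraries alone 176 (LYVE1+). Leaving out single libraries gave 23 to 64 (aorta), 219 to 1025 (fat), 494 to 1635 (average), 0 to 47 (interaction), 172 to 443 (LYVE1+) and 98 to 385 (LYVE1-).

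Lists called with an estimated correlation were 0 (aorta), 1 (fat), 0 (average), 1 (interaction), 0 (LYVE1+) and 0 (LYVE1-), and in LYVE1- cells 9 to 19 lists were called without single libraries, 9 of them without fat LYVE1- library 1. With the replicate block the hyaluronan list of the aorta (0.078) and the lipid list of the average (0.071) were no longer called. Over genes called in at least 1 comparison the LYVE1 effects of the tissues correlated at 0.624 and the tissue effects of the sorts at 0.7, and the latter was 0.316 to 0.497 over all genes without single libraries.

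Of 7484 values of named genes under other settings 6448 kept their call or lack of one, 939 lost a call, 97 gained one and 0 were called in the opposite direction, while 256 values without a call changed sign. Of the 220 calls 41 were kept under every setting. The prefix ended 115 and the 2-fold test 162.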

Other observations

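The tests of the patterns below, and their limits, were chosen after the values were seen, and some limits were changed afterwards, as stated with each.

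Heme, sugar and interferon genes differed between the tissues by single members rather than as lists. Among LYVE1+ cells Spic, the heme-induced factor of red pulp macrophages, was 2.21-fold higher in the aorta than in fat, Hk2, the inducible hexokinase, 4.05-fold, and Ifit1, an interferon-induced RNA sensor, 14.7-fold. These calls held with the library prefix in the model (adjusted p = 0.026, 0.014 and 0.014). Among LYVE1- cells Spic was 2.01-fold, Hk2 3.03-fold and Ifit1 10-fold higher, and none of these calls held with the prefix: the log2 fold change moved from 1.01 (SE 0.19) to 1.14 (SE 0.36, adjusted p = 0.63) for Spic, from 1.6 (SE 0.28) to 1.52 (SE 0.54, adjusted p = 0.7) for Hk2 and from 3.33 (SE 0.56) to 2.1 (SE 0.89, adjusted p = 0.76) for Ifit1. Without fat LYVE1- library 3 they were not called either (0.08, 0.068 and 0.054), nor was Spic without aorta LYVE1- library 3 (0.073). Other members went both ways in LYVE1- cells. Eno1 of the glycolysis list (log2 fold change -0.627, SE 0.13, adjusted p = 0.027) and Slc48a1 of the heme list (-0.672, SE 0.12, adjusted p = 0.013) were lower in the aorta. Pfkfb3, Fth1, Hmox1 and Ifih1 were higher there. With the prefix in the model none of these calls held. For LYVE1- cells that prefix term was estimated from the aorta LYVE1+ libraries alone. In fat the bone morphogen Bmp2 was 2.58-fold higher in LYVE1+ than LYVE1- cells (adjusted p = 0.0037), and Lgals3, a lectin of lipid-laden macrophages, had a log2 fold change of -1.14 (adjusted p = 0.0018).

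Gate genes, interferon, glycolysis, endothelial, large peritoneal macrophage and erythroid lists were called in no comparison. Adjusted p in the order aorta, fat, average, interaction, LYVE1+ and LYVE1- was 0.16, 0.43, 0.18, 0.97, 0.19 and 0.19 for gate genes, 0.65, 0.29, 0.3, 0.62, 0.37 and 0.097 for interferon, 0.74, 0.48, 0.77, 0.54, 0.12 and 0.62 for glycolysis, 0.4, 0.92, 0.61, 0.74, 0.8 and 0.31 for endothelial, 0.26, 0.77, 0.45, 0.71, 0.33 and 0.73 for peritoneal, and 0.97, 0.68, 0.77, 0.78, 0.058 and 0.15 for erythroid genes. Median, mean and test differed in sign for interferon, glycolysis and erythroid genes in the aorta, endothelial genes in fat and the average, and glycolysis in the interaction. Neutrophil markers, with 3 measured, were not tested.

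Other lists without a call were these. In the aorta they were scavenger receptors (0.18, Axl lower), growth factors (0.31), cell cycle (0.26), iron (0.093), smooth muscle (0.59) and adipocyte (0.24) genes. In fat they were hyaluronan (0.44, 3 higher and 2 lower of 13), matrix protease (0.48, 2 higher and 1 lower of 23), scavenger (0.089, 4 higher and 3 lower of 17), chemokine (0.06, 1 higher and 3 lower of 21), growth factor (0.88, 3 higher and 1 lower of 20), immediate early (0.43, 2 lower of 24), lipid (0.08, 7 lower of 19), oxidative phosphorylation (0.079), dendritic (0.87, 3 higher of 13), smooth muscle (0.48), fibroblast (0.097, 1 lower of 10), lymphatic endothelial (0.076, median 5.2 and 2.6 at bound, 1 higher of 5), adipocyte (0.51), T and NK (0.48), B (0.48), mast (0.48) and eosinophil (0.83) genes, with sign differences for hyaluronan, dendritic and eosinophil genes. The lymphatic gene called in fat was Prox1, a regulator of lymphatic fate, with a log2 fold change of 5.58 (SE 1.1, adjusted p = 0.014). Prox1 had 4.031, 1.387 and 1.109 CPM in fat LYVE1+ libraries 1, 2 and 3 (mean 2.175). The fat LYVE1- group held 1 count, so the size of this fold is uncertain. Without fat LYVE1- library 3 it was not called (0.062). In the average they were hyaluronan (0.23, 3 higher and 2 lower), matrix protease (0.081, 2 higher and 5 lower), scavenger (0.072, 5 higher and 2 lower), growth factor (0.61, 5 higher and 2 lower), immediate early (0.081, 2 lower), dendritic (0.12, 2 higher and 2 lower), smooth muscle (0.79), adipocyte (0.25), T and NK (0.58) and B (0.5) genes.

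In the interaction the lists without a call were class II (0.16), monocyte (0.97), hyaluronan (0.96, Hmmr higher), matrix protease (0.24), scavenger (0.54), complement (0.075), chemokine (0.97), inflammatory (0.74), growth factor (0.71), immediate early (0.62), lipid (0.9), iron (0.66), ribosomal (0.17), smooth muscle (0.44), fibroblast (0.97), lymphatic endothelial (0.78) and adipocyte (0.83) genes. There the sign of median, mean and test differed for monocyte, hyaluronan, chemokine, growth factor, lipid, fibroblast and lymphatic endothelial genes. Between LYVE1+ cells of the tissues they were resident (0.37, 2 lower of 22), matrix protease (0.25, 1 higher), scavenger (0.21, 1 higher), complement (0.63), chemokine (0.088, with 5 higher and 2 lower of 21), immediate early (0.69, with 3 higher and 2 lower of 24), lipid (0.06, 3 lower of 19), iron (0.92, 2 higher of 12), oxidative phosphorylation (0.55), ribosomal (0.45), dendritic (0.14, 1 higher and 1 lower) and T and NK (0.07, 1 higher and 1 lower) genes. Between LYVE1- cells they were class II (0.26), complement (0.097), inflammatory (0.15, 1 higher), immediate early (0.26, 3 higher and 2 lower of 24), iron (0.6, 3 higher and 1 lower of 12), ribosomal (0.34), dendritic (0.11, 1 higher), T and NK (0.62, 1 higher), B (0.62) and eosinophil (0.26, 1 higher) genes, with sign differences for iron, T and NK and eosinophil genes.

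Class II transcripts put fat LYVE1+ library 1 between the fat groups, at a median of 19.7% of the way to LYVE1- cells over 7 genes, where 96 other genes lower in LYVE1+ cells lay at a median of 25.7% (quartiles -3.23 and 66.2). LYVE1- macrophages in that sort may be the source: 2 of the others, Axl (44.53 CPM) and Vcam1 (62.76 CPM), lay below the level their share would bring, fewer than the limit of 3, so this stays open. The first rule, which was replaced after its value was seen, counted 34.4% of genes less than 0.5 times as far as class II against a limit of 25% and would have argued against it. B cells and dendritic cells may be a source too, since 13 of 21 of their markers were above both other fat LYVE1+ libraries, though the gate on CD64, MerTK and F4/80 would remove them. B markers exceeded by 624 CPM and class II by 9310 CPM, Ighm was not raised (832.4 CPM), and this stays open as well.

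Lyve1 transcript remained in LYVE1- cells at 24.4% of the LYVE1+ level in fat (11.9% to 31.7%) and 40.4% in the aorta (34.3% to 52.3%), and LYVE1+ cells carried over into that sort may be the source. As the whole source this is argued against in fat, where 3 of 14 genes chosen by their call in the aorta had a log2 fold change above that of Lyve1 beyond the SE of both (the limit was 3): Adgrg1 by 2.86 (SE 0.55, adjusted p = 0.0057), Npr1 by 2.13 (SE 0.5, 0.0081) and Vsig4 by 2.45 (SE 0.6, 0.0081), which kept at most 4.64%, 9.33% and 5.32%. In the aorta it stays open, since 0 of 201 genes chosen by their call in fat passed this test: the largest excess was that of Vsig4, 1.56 (SE 0.54, adjusted p = 1), although Vsig4 kept at most 18.9% there, and Aqp1, which was not called in fat and so not in this test, kept at most 17.8%. This is the fourth version of the test and was chosen after values were seen; counts of called genes below the lowest Lyve1 share gave 3 in fat, open with a first limit of 10 and against with a later one of 3, and 6 of 15 in the aorta, against, and counts below 0.5 times the share gave 3 in fat, against, and 0 in the aorta, open. The 3 genes did not keep their calls in the aorta, which chose them, without each single library, and Lyve1 transcription in cells without surface LYVE-1 was not tested.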
